A study of Mus musculus with 6 samples.

How the data were processed

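Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse NIH/3T3 embryonic fibroblasts that carried a knock-in of Cas13d, a CRISPR enzyme that cuts RNA rather than DNA. Per the labels, 3 libraries came from cells given a guide RNA against the Actg1 mRNA and 3 from cells given a guide against GFP, which served as the control, and each library was made from 25000 cells with a transposition of 30 min at 37 °C and paired-end sequencing. The labels describe the 3 libraries of each group as biological replicates and do not say whether they came from separate cultures. The p-values measure the spread between these samples, which lay close to counting error, as given below, and may be largely technical.

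Per the submitters' processing notes, the genome build was mm10 and the tools were Trimmomatic 0.39, STAR 2.7.10a, Picard 3.0.0, featureCounts, DESeq2 1.36.0 and DESeq, with no roles stated. The peak caller, the rule for merging peaks, the handling of the Tn5 offset, the gene annotation version and the normalization formula are not given in the sources used here. The authors deposited a table of 63430 regions with 1 signal value per region and library, in which the signal is a read count that had been normalized and rounded to whole numbers. This reading of the unit rests on the values: the totals of the 6 columns lay between 7673745 and 7831438, and the small values showed the uneven use of whole numbers that a rounded multiplication leaves. The regions had a median length of 354 bp. The table assigned 21566 regions to a gene, with at most 1 gene per region and at most 5988 bp between region centre and transcription start site (TSS), so a promoter shared by neighbouring genes carries 1 name. A gene symbol was given for 15117 regions. Coordinates are those of the table and start from 1 as printed there. The gene bounds of Actg1 and Actg2 came from a RefSeq gene table of the same build, which gives no strand.

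The unevenness of the small values gave an estimate of the signal that 1 read is worth in each library, between 0.807 and 1.35, and from it the reads in regions, which ranged from 5675931 to 9526231. On simulated columns the largest error of this factor was 8e-05. These estimated reads were used to compare replicates and in 1 alternative test. GFP guide replicates 1 and 2 differed by less than the sampling noise, with a chi-square per region of 0.990 (p = 0.947, 50824 regions), while the other within-group pairs gave 1.04 to 1.13. The lowest of those, Actg1 guide replicates 2 and 3 at 1.04, was kept as 2 samples, although every within-group pair lay near counting error. This chi-square sets counting error alone as the expected spread, and its reads are approximate: 36.8% of the values of GFP guide replicate 1 fit 2 or more read counts. GFP guide replicates 1 and 2 were therefore averaged and counted as 1 sample, which left 2 GFP guide samples and 3 Actg1 guide samples. Every SD of the GFP guide is between that mean and replicate 3. It leaves out the spread between replicates 1 and 2 and can be far below the spread of the 3 libraries. This averaging was decided after the fit with 6 separate libraries had been seen, and the counts of that fit are given with the results.

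The design fixed before the data were examined named a count-based test for raw counts and limma for normalized values. As the values were normalized, limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend to log2(signal + 1). Fold changes are on that scale, which understates changes of low regions, and are the Actg1 guide over the GFP guide. Regions with a signal of at least 10 in at least 3 of the 6 libraries were tested, which kept 61327 and left out 2103. P-values were adjusted by the Benjamini-Hochberg method, and a region was called at an adjusted p under 0.05. No covariate was used. On simulated values for this comparison over 61327 regions, limma called 0 regions when none was changed. With 200 regions changed, it called 6% of those at 1.25-fold, 66% at 1.5-fold, 72% at 2-fold and 84% at 3-fold, and 0.87% of the calls were false. In the data 41.3% of regions were called, so the adjustment admits larger p-values and these shares do not carry over. The simulated libraries varied little beyond counting error, and GFP guide replicates 1 and 2 were drawn from 1 library. No difference between cultures was put in. The 0 calls with no region changed therefore do not show how often limma calls falsely where cultures differ. A promoter region was one whose centre lay within 1 kb of the TSS of its assigned gene. Promoter and other regions were compared by a two-sided Fisher's exact test, although neighbouring regions are not independent. Summed signal over a locus was compared by an exact two-sided permutation test, whose smallest possible p with 2 against 3 samples is 0.1. The design named the 10 kb before each gene's start; without strand, 10 kb on either side were taken.

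Before the data were examined, 20 gene lists of 384 genes were fixed. They covered actin isoforms, actin regulators, SRF/MRTF targets, YAP/TEAD targets, immediate early genes, interferon response, NF-kB inflammatory genes, p53 targets, ATF4 and unfolded protein response genes, mRNA decay factors, the H3K4 methyltransferase complex, fibroblast and matrix genes, cell cycle genes, ribosomal protein genes, and markers of skeletal and cardiac muscle, adipocytes, epithelium, endothelium, blood cells and neurons. Of these genes, 249 had a tested promoter region. The lists were tested among the 11650 promoter regions with camera at a preset correlation of 0.01 and at an estimated one, and with fry. On simulated values over 61327 regions, camera called the 1 list that had been raised, 25 regions at 1.3-fold, and 0 of the other 19. The lists in the data had 1 to 25 promoter regions. Smaller lists, smaller shifts and lists with members changing both ways were not simulated. Nor was a background in which as many promoters change as in the data. The simulation therefore does not show how often camera would miss a shifted list in the data.

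The rule for named regions, also fixed beforehand, took the regions of the actin genes and of the Actg1 and Actg2 loci, the 12 largest rises and 12 largest falls among called regions whose groups did not overlap, and the 3 promoter regions with the smallest p in each list. A further 15 rises and 15 falls at protein-coding promoters were chosen after the values had been seen, because the largest changes lay outside promoter regions. Alternatives covered the scaling, the low-signal filter, the test, the pseudocount, the thresholds, the windows, the replicate number as a block and each library left out in turn. The count-based tests were not run because the values are not raw counts. Corrections for GC content, sets of regions with binding motifs and genes similar in sequence to the Actg1 mRNA were not analysed here, because they need a genome or transcript sequences, which were not used here. Figures were drawn with matplotlib 3.10.9.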

Results

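The data were accessibility profiles of mouse NIH/3T3 fibroblasts, a cell line derived from mouse embryos, in which the RNA-cutting enzyme Cas13d was given a guide against the mRNA of Actg1, the gene of cytoplasmic gamma-actin, or a guide against GFP as control. The stated purpose was to learn what part mRNA degradation plays in transcriptional adaptation, a response in which decay of a mutant or targeted mRNA is accompanied by higher transcription of related genes. Each group had 3 libraries. Estimated reads in regions were 9472514, 6785497 and 8120024 for GFP guide replicates 1, 2 and 3, and 9526231, 5675931 and 6243389 for Actg1 guide replicates 1, 2 and 3. GFP guide replicates 1 and 2 differed by less than the sampling noise and were counted as 1 sample, so the SDs of that group leave out the spread between them. No region took more than 0.128% of a library's signal. The log2 signals correlated across regions at 0.972 to 0.981 within groups and at 0.900 to 0.917 between groups, and the first principal component, with 72.1% of the variance, separated the groups.

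The targeted gene came first. Among the regions used here, 0 lay in the body of Actg1 (chromosome 11, 120345687 to 120348495) or within 10 kb of it, so accessibility of its promoter was not analysed here, and these data do not measure the level of its mRNA. Within 50 kb lay 2 regions. The promoter of Faap100, a component of the Fanconi anaemia core complex, had a signal of 177 ± 17.3 (SD, n = 2) with the GFP guide and 196 ± 11.8 (SD, n = 3) with the Actg1 guide, a log2 fold change of 0.15 that did not pass (limma adjusted p = 0.238). The region at 120369799 to 120370107, assigned to no gene, had 19.5 ± 2.12 and 30.3 ± 1.15, a log2 fold change of 0.62 (SE 0.248, limma adjusted p = 0.0428). That call ended when any of 5 libraries was left out: the limma adjusted p was 0.125 without GFP guide replicate 2, 0.096 without GFP guide replicate 3, and 0.0658, 0.0724 and 0.0739 without Actg1 guide replicates 1, 2 and 3, and it was 0.0654 after cyclic loess scaling. The summed signal of both regions differed by 0.21 on the log2 scale (exact permutation p = 0.2, where 0.1 is the smallest possible).

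Actg2 encodes the gamma-actin of smooth muscle and is the paralogue whose induction is measured in studies of this response. Of the regions used here, 0 lay in its gene body (chromosome 6, 83512909 to 83536251), and 1 lay within 10 kb, the promoter of Dguok, which encodes mitochondrial deoxyguanosine kinase. Dguok had a signal of 567.5 ± 20.5 (SD, n = 2) with the GFP guide and 580 ± 26.1 (SD, n = 3) with the Actg1 guide, a difference of 0.03 on the log2 scale that was smaller than the spread (exact permutation p = 0.6). It had no stable direction, at -0.0045 without GFP guide replicate 1, -0.0051 without GFP guide replicate 3 and 0.07 without GFP guide replicate 2. Within 50 kb lay 4 regions, whose summed signal differed by 0.11 (exact permutation p = 0.3). A region at 83478743 to 83479077, assigned to no gene, rose from 26.5 ± 3.54 to 102 ± 5.69, which is 3.75-fold (log2 fold change 1.91, SE 0.165, limma adjusted p = 2.16e-12). Its values were 23, 25 and 29 in the GFP guide libraries and 97, 100 and 108 in the Actg1 guide libraries. It lay 33.8 kb from Actg2 and nearer to Dguok than to Actg2. The promoter of Stambp, a deubiquitinase, had a log2 fold change of -0.17 (limma adjusted p = 0.168) and the remaining region, at 83583003 to 83583158, one of -0.24 (limma adjusted p = 0.51).

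**Figure D1:**
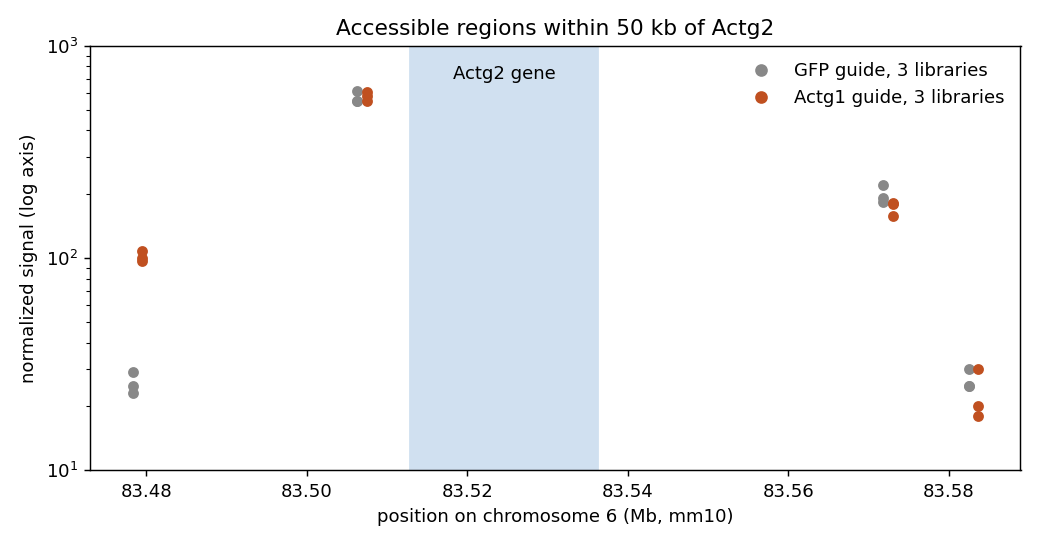
Normalized signal (log axis) of the 4 accessible regions within 50 kb of Actg2 against position on chromosome 6 in Mb (mm10), with 1 point per library, 3 libraries per guide, points of the guides set slightly apart sideways and the gene shaded. The region at the left has 23 to 29 with the GFP guide and 97 to 108 with the Actg1 guide, while the ranges of the guides overlap at the Dguok promoter.

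Of the other actin genes, 2 had regions. The promoter of Actb, the gene of cytoplasmic beta-actin (chromosome 5, 142905692 to 142906996), rose from 1022 ± 16.6 (SD, n = 2) to 1198 ± 32.3 (SD, n = 3), which is 1.17-fold (log2 fold change 0.23, SE 0.0435, limma adjusted p = 3.68e-05). All 3 Actg1 guide libraries (1171, 1234 and 1190) lay above the 3 GFP guide libraries (1017, 1050 and 1010). A second Actb region, 3155 bp from the TSS, had a log2 fold change of -0.09 (limma adjusted p = 0.594). The promoter of Acta2, the smooth muscle alpha-actin gene (chromosome 19, 34254217 to 34255807), had 203 ± 15.2 and 203 ± 13.1, a log2 fold change of 0.00 (limma adjusted p = 0.977). Regions of Acta1 and Actc1 were not analysed here.

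Across the genome, the comparison asked where accessibility differs between cells given the Actg1 guide and cells given the GFP guide. Of 61327 tested regions, 12642 were higher and 12681 lower with the Actg1 guide, together 25323 or 41.3% (limma, adjusted p under 0.05). The spread within groups lay close to counting error (chi-square per region 0.990 to 1.13). These calls therefore may not allow for variation between cultures. At least 2-fold changes were called in 3760 regions upward and 3701 downward. The groups did not overlap in 36100 regions, or 58.9%, where chance gives 20% for 2 against 3 samples. With the 6 libraries as separate samples, chosen after seeing the data, the counts were 14071 higher and 14105 lower. Without GFP guide replicate 3, which left 1 GFP guide sample, 7381 were higher and 5412 lower. Of the regions named here and below, 36 calls ended without that library. In 27 of them the log2 fold change kept at least 80% of its main value. In the other 9 (Tnc, Jun, Fbln2, Pnpla2, Hoxd13, Tap2, Col16a1, Ccng1 and Srf) it kept 48.2% to 79%. The standard errors of the 36, with 1 GFP guide sample left, were 1.08 to 1.64 times the main ones.

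Promoters changed less often, and by less, than other regions. Of 11650 promoter regions, 1631 were higher and 2175 lower, together 32.7%, against 11011 higher and 10506 lower of 49677 other regions, together 43.3% (odds ratio 0.635, 95% interval 0.608 to 0.663, two-sided Fisher's exact p = 6.79e-100). Without GFP guide replicate 3 the odds ratio was 0.39 (95% interval 0.366 to 0.416). At least 2-fold changes were called at 285 promoter regions (2.45%) and 7176 other regions (14.4%), an odds ratio of 0.148 (95% interval 0.131 to 0.168). Promoters of protein-coding genes made up 9954 of the promoter regions, and of these 44 rose and 55 fell by at least 2-fold. The median signal was 245 at promoters and 44.7 elsewhere. In the quintile of regions with the highest signal, 35.2% of promoter regions and 50.7% of other regions were called. The median absolute log2 fold change there was 0.12 at promoters and 0.19 elsewhere, and in the lowest quintile 0.46 and 0.59. In that lowest quintile, 18.6% of promoter regions and 28.4% of other regions were called with at least 2-fold changes. At like signal the gap in median size was thus smaller than over all regions. The gap in the share called was wider at high signal. In quintile 4, next to the highest, 28.6% of promoter regions and 51.4% of other regions were called. Changes of at least 2-fold were called at 0.0292% of promoter regions and 0.849% of other regions in the highest quintile.

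**Figure D2:**
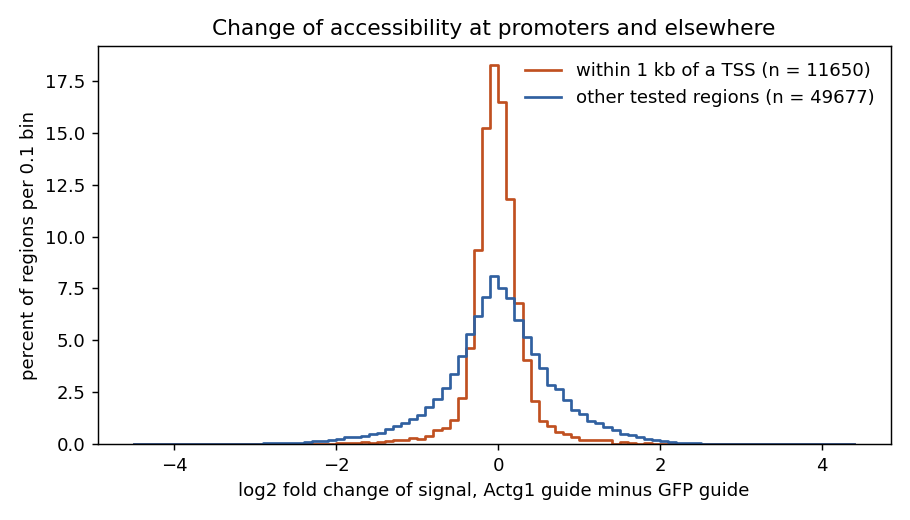
Percent of regions per bin of 0.1 (y axis) against the log2 fold change of signal, Actg1 guide minus GFP guide (x axis), for 11650 promoter regions and 49677 other tested regions. The distribution is narrower at promoters, whose median absolute log2 fold change was 0.15 against 0.38 elsewhere, without matching for signal, which is higher at promoters.

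The largest changes by log2 fold change lay away from annotated promoters. They were mostly at regions of low signal, where few regions are promoters. The lowest quintile of signal held 582 promoter regions and 11684 other regions. Among the 12 largest rises, the region at 32366756 to 32367637 on chromosome 12, 11.2 kb from Ccdc71l, went from 10.8 ± 5.30 (SD, n = 2) to 105 ± 10.7 (SD, n = 3), with a log2 fold change of 3.25 (limma adjusted p = 1.13e-15). The region at 29490523 to 29491308 on chromosome 16, within Atp13a4, a P5-type ATPase gene, went from 12.8 ± 1.77 to 108 ± 11.9 (log2 fold change 2.98, limma adjusted p = 2.75e-16). The region at 50855105 to 50855512 on chromosome 1, 45.2 kb from Tmeff2, went from 6.25 ± 2.47 to 54 ± 10. The others of the 12 lay in Negr1 and Crxos or nearest to Slc6a13, Pappa, Tmem252, Rgs7bp, Rpl28, Atp11b and Mapk4, with log2 fold changes of 2.88 to 3.24. Among the 12 largest falls, the region at 18186039 to 18186243 on chromosome 16, 28.0 kb from Ccdc188, went from 42 to 3 ± 2 (log2 fold change -3.56, limma adjusted p = 2.8e-08). The region at 102553953 to 102554286 on chromosome 10, 4.22 kb from Rassf9, went from 37.2 ± 1.77 to 2.67 ± 1.15. In 2 regions all Actg1 guide libraries were listed at 0: the region at 156772442 to 156772700 on chromosome 1, nearest to Ralgps2, with 16, 26 and 14 in the GFP guide libraries, and the region at 123463814 to 123463939 on chromosome 9, nearest to Lars2, with 13, 16 and 11. The others lay in Svil, Trio, Akap13, Zc2hc1a and Scara3 or nearest to Mme, Dph6 and Ankrd50. Without GFP guide replicate 3, the calls of the regions nearest to Lars2, in Trio and in Zc2hc1a ended at log2 fold changes of -3.95, -3.69 and -3.62 (limma adjusted p = 0.0638, 0.0534 and 0.0655).

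Among protein-coding promoters, chosen for naming after the values had been seen, the 15 largest rises had log2 fold changes of 1.35 to 1.95. They included Rarb, the retinoic acid receptor beta gene, which went from 28.2 ± 0.354 (SD, n = 2) to 73.7 ± 1.53 (SD, n = 3), Cd74, the invariant chain of class II antigen presentation, from 15 ± 1.41 to 41 ± 4.36, and Atp13a4, from 24.5 ± 0.707 to 75.7 ± 14.4. The 3 GFP guide libraries of Rarb had 25, 32 and 28, a wider spread than the SD of the 2 samples shows. Natd1 went from 45.8 ± 2.47 to 125 ± 13.2, and Bpifc, Ccdc63, Sprr1a, Ccdc117, Sh2b2, Sf3a1, Zfp119b, Nrip2, Treml4, Serpinb9e and a gene without a symbol were the others. The 15 largest falls had log2 fold changes of -2.61 to -1.50. Among them, Prelp, a leucine-rich proteoglycan, went from 21.5 ± 0.707 to 3 ± 1.73, Aspn (asporin) from 36.5 ± 4.95 to 11 ± 1, and Col6a3, a chain of type VI collagen, from 72.2 ± 4.60 to 22 ± 1.73. Of the rest, Tnni1, slow skeletal troponin I, went from 44.2 ± 1.06 to 12.3 ± 3.21, Ldb3, a Z-disc protein, from 47.2 ± 7.42 to 15.3 ± 5.86, and Dmpk, myotonic dystrophy protein kinase, from 60 ± 5.66 to 20.7 ± 2.31. Apod, Aox1, Mettl21c, Ecrg4, 4933402D24Rik, Slc39a12, Smim11a, Gm5737 and Xpnpep2 were the others. Some of these genes have a second promoter region that did not pass. The regions nearer to the TSS of Ccdc117, Sf3a1, Smim11a and Dmpk had log2 fold changes of 0.08, 0.21, 0.10 and -0.12 (limma adjusted p = 0.517, 0.115, 0.507 and 0.255). The one farther from the TSS of Cd74 had 0.11 (limma adjusted p = 0.81). The calls of Smim11a, Gm5737 and Xpnpep2 ended without GFP guide replicate 3, at log2 fold changes of -2.04, -1.59 and -1.36 (limma adjusted p = 0.0758, 0.0958 and 0.0669).

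No list passed the test of a shift against the other promoters. Camera called 0 of the 20 gene lists at an adjusted p under 0.05, with the preset and with the estimated correlation, and the smallest adjusted p was 0.257 and 0.612, respectively. Fry, which asks whether a list's members move on balance in a single direction without reference to other genes, called 5 lists, and its mixed test, which asks whether members change either way, called 15. The fry calls depended on the processing. With a promoter window of 5 kb, 0 of the 5 lists were still called, and muscle markers were called instead (fry adjusted p = 0.0329). Of the 5 lists, 0 were still called without Actg1 guide replicate 1 or 2, and 1 without GFP guide replicate 3 or Actg1 guide replicate 3. Counts below are of promoter regions over all regions tested, and the count adjusted over the list alone was the same unless given. Over all 11650 promoter regions 32.7% were called, so called members alone do not set a list apart. Among lists of at least 14 regions, the share called ran from 14.3% (mRNA decay factors) to 56.5% (interferon response). Without GFP guide replicate 3 the count of called regions was less than the main count by over 1.5 times in 15 of the 20 lists.

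Genes of the actin cytoskeleton changed both ways. Of 25 promoter regions of actin regulators, 3 were higher and 6 lower (camera adjusted p = 0.717). The promoter of Pfn1 (profilin, which binds actin monomers) rose from 546 ± 11 (SD, n = 2) to 771 ± 47.6 (SD, n = 3) and that of Cfl1 (cofilin, which severs filaments) from 474.5 ± 2.12 to 617 ± 20.1, while Cap1 (cyclase-associated protein) fell from 895 ± 8.13 to 728 ± 22.9. Of 16 promoter regions of SRF/MRTF targets, genes driven by the actin-sensitive cofactor MRTF, 1 was higher and 7 lower, and adjusted over the list alone 2 were higher and 7 lower (camera adjusted p = 0.429, fry adjusted p = 0.0216 downward, and 0.0549 with the 5 kb window). Tagln (transgelin) fell from 148 ± 4.60 to 110 ± 2.65 and Tagln2 from 966 ± 20.2 to 835 ± 46.9, while Srf itself rose from 645 ± 24.4 to 733 ± 21.5. Of 20 regions of YAP/TEAD targets, 7 were higher and 4 lower, and adjusted over the list alone 7 were higher and 5 lower (camera adjusted p = 0.508). Ankrd1 rose from 75.8 ± 4.60 to 136 ± 7.23 and Arhgef17 by 0.38 on the log2 scale, and Ccdc80 fell from 192 ± 6.36 to 114 ± 4.58. Second promoter regions of Pfn1, Cap1 and Ccdc80, with lower signal, had log2 fold changes of 0.05, 0.09 and 0.21 that did not pass (limma adjusted p = 0.827, 0.702 and 0.647). Of the 2 promoter regions of actin isoforms 1 was higher (camera adjusted p = 0.429). Leaving out GFP guide replicate 3 ended the calls of Tagln2 and Srf, at log2 fold changes of -0.19 and 0.14 (limma adjusted p = 0.0804 and 0.139). It left 2 regions higher and 1 lower among actin regulators, 0 and 1 among SRF/MRTF targets, and 3 and 2 among YAP/TEAD targets. Actin regulators had 2 higher and 3 lower without Actg1 guide replicate 2, and SRF/MRTF targets 1 and 4 without Actg1 guide replicate 3.

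**Figure D3:**
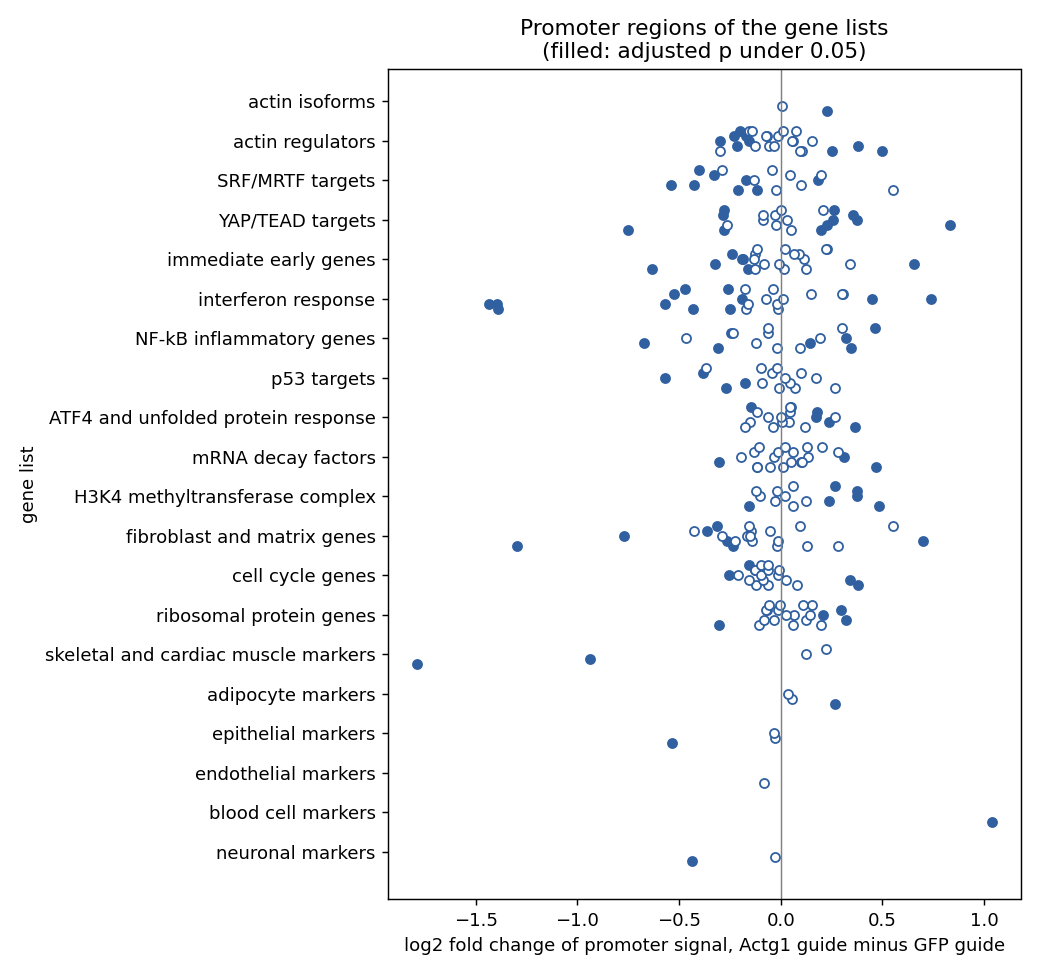
Log2 fold change of signal, Actg1 guide minus GFP guide (x axis), for each promoter region of the 20 gene lists (y axis), with filled points for an adjusted p under 0.05 and vertical offsets within a list for legibility. Members lie on both sides of 0 in most lists, and the interferon list reaches from -1.43 to 0.74.

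Among stress and signalling lists, the interferon response had the most called regions, with 3 higher and 10 lower of 23, and adjusted over the list alone 4 higher and 10 lower (camera adjusted p = 0.266, fry adjusted p = 0.0271 downward, but upward at 0.413 with the 5 kb window). Zbp1, a nucleic acid sensor, fell from 169 ± 3.18 (SD, n = 2) to 64.7 ± 13.1 (SD, n = 3) and Mx1, an antiviral GTPase, from 102 ± 7.42 to 37.7 ± 9.07, while the chemokine gene Cxcl10 rose from 228 ± 4.60 to 313 ± 27.0. Immediate early genes had 2 regions higher and 6 lower of 22 (camera adjusted p = 0.429), with falls at Nr4a1 (312 ± 0.354 to 201 ± 11.3), Klf2 (837 ± 17.3 to 669 ± 33.1) and Jun (log2 fold change -0.19). NF-kB inflammatory genes had 4 higher and 3 lower of 16 (camera adjusted p = 0.636), where Nfkb2 rose by 0.34 and Il6 by 0.32 on the log2 scale and Ccl7 had a log2 fold change of -0.67; the list's median was -0.04 and camera's direction was up. Of 16 regions of p53 targets 0 were higher and 4 lower (camera adjusted p = 0.508), among them Ccng1 (-0.27), Plk2 (-0.18) and the region of Tnfrsf10b 719 bp from its TSS (-0.57). The Tnfrsf10b region 89 bp from the TSS had 118 ± 7.42 and 142 ± 6.66, a log2 fold change of 0.27 that did not pass (limma adjusted p = 0.0557). ATF4 and unfolded protein response genes had 4 higher and 1 lower of 18 (camera adjusted p = 0.374), with rises at Xbp1 (0.37), Vegfa (0.24) and Herpud1 (0.17). The calls of Jun, Il6, Ccng1, Plk2 and Herpud1 ended without GFP guide replicate 3, at log2 fold changes of -0.11, 0.29, -0.21, -0.14 and 0.18 (limma adjusted p = 0.138, 0.111, 0.128, 0.115 and 0.0783). That left 2 regions higher and 4 lower in the interferon list, 0 and 3 among immediate early genes, 1 and 1 among NF-kB genes, 0 and 1 among p53 targets, and 2 and 0 among ATF4 and unfolded protein response genes. Immediate early genes had 0 higher and 5 lower without Actg1 guide replicate 1 and 0 and 4 without Actg1 guide replicate 2, and ATF4 and unfolded protein response genes 3 and 0 without the latter.

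Factors of mRNA decay and the complex that methylates histone H3 at lysine 4 have both been proposed to act in transcriptional adaptation. Of 21 promoter regions of mRNA decay factors 2 were higher and 1 lower (camera adjusted p = 0.429). Upf1, the helicase of nonsense-mediated decay, rose from 180.5 ± 14.8 (SD, n = 2) to 250 ± 16 (SD, n = 3) and Smg9 from 219 ± 1.77 to 272 ± 11, and the deadenylase gene Cnot6 fell from 338 ± 12.7 to 274 ± 18.3. Of 14 regions of the H3K4 methyltransferase complex 5 were higher and 1 lower, and adjusted over the list alone 6 were higher and 1 lower (camera adjusted p = 0.266). The methyltransferase genes Setd1a (274 ± 34.3 to 383 ± 19.4), Kmt2a (478 ± 16.6 to 563 ± 24.0) and Setd1b (135 ± 7.07 to 175 ± 6.11) rose. The calls of Smg9, Cnot6 and Kmt2a ended without GFP guide replicate 3, at log2 fold changes of 0.30, -0.27 and 0.20 (limma adjusted p = 0.0607, 0.0999 and 0.0889). That left 1 region higher and 0 lower among decay factors and 2 and 0 in the methyltransferase complex. The count of decay factors was larger under other alternatives, with 5 higher and 1 lower after cyclic loess, 4 and 1 after total scaling, 4 and 2 with voom or without GFP guide replicate 2, and 3 and 3 with the replicate block.

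Fibroblast and matrix genes had 1 region higher and 6 lower of 22 (camera adjusted p = 0.257, and 0.612 with an estimated correlation; fry adjusted p = 0.0216 downward, and 0.155 with the 5 kb window). Of the type I collagen genes, Col1a2 fell from 252 ± 3.89 (SD, n = 2) to 148 ± 2.89 (SD, n = 3). The region of Col1a1 centred 823 bp from the TSS rose from 255 ± 1.41 to 417 ± 44.5. The Col1a1 region 20 bp from the TSS, with 105.5 ± 19.1 and 112 ± 11.4, had a log2 fold change of 0.09 that did not pass (limma adjusted p = 0.605). S100a4, a fibroblast calcium-binding protein, fell from 177 ± 8.84 to 72.3 ± 13.5. Cell cycle genes had 2 higher and 3 lower of 19, and adjusted over the list alone 2 higher and 1 lower (camera adjusted p = 0.49), with Aurkb at 0.38, Top2a at 0.34 and Ccnb1 at -0.26 on the log2 scale. Ribosomal protein genes had 3 higher and 1 lower of 20, and adjusted over the list alone 2 higher and 1 lower (camera adjusted p = 0.429), with Rps6 at -0.30, Rpl23 at 0.32 and Rpl27 at 0.21. Without GFP guide replicate 3 these 6 calls ended although the log2 fold changes were 0.33, 0.32, -0.24, -0.31, 0.30 and 0.17, with limma adjusted p of 0.052 for Aurkb, 0.0632 for Top2a, 0.0704 for Ccnb1, 0.0542 for Rps6, 0.15 for Rpl23 and 0.171 for Rpl27. That left 0 called regions in the cell cycle and ribosomal lists, and 1 region higher and 3 lower among fibroblast and matrix genes. Cell cycle genes had 2 higher and 1 lower without Actg1 guide replicate 1 or 2, after cyclic loess and after total scaling. The call of Rpl27 also ended without GFP guide replicate 2 (limma adjusted p = 0.146) and that of Rpl23 without Actg1 guide replicate 2 (limma adjusted p = 0.0765).

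Markers of other cell types had few promoter regions. Muscle markers had 0 higher and 2 lower of 4 (camera adjusted p = 0.429): Tnni1, given above, and Tnnt3, fast troponin T, which fell from 55.8 ± 5.30 (SD, n = 2) to 28.7 ± 3.06 (SD, n = 3), while Mylpf had a log2 fold change of 0.12 that did not pass (limma adjusted p = 0.113). It passed, upward, with the replicate block (0.0328), 6 separate libraries (0.0435), voom (0.00759) and cyclic loess (0.0302). The only blood cell marker with a region, Cd68, rose from 49 ± 9.90 to 101 ± 10.5 (camera adjusted p = 0.257, fry adjusted p = 0.0466, and 0.0549 with the 5 kb window). Of 2 neuronal markers, Map2 fell from 243 ± 11.7 to 179 ± 8.08 and Tubb3 had a log2 fold change of -0.03 that did not pass (camera adjusted p = 0.429). Of 3 adipocyte markers 1 was higher, Pnpla2 at 0.27, with Cebpa at 0.06 and Scd1 at 0.04 (camera adjusted p = 0.429, fry adjusted p = 0.0271, and 0.0788 with the 5 kb window). Of 3 epithelial markers 1 was lower, Krt19 at -0.53, with Krt8 and Krt14 at -0.03 each (camera adjusted p = 0.636), and the 1 endothelial marker, Erg, had a log2 fold change of -0.08 that did not pass (camera adjusted p = 0.91). The call of Pnpla2 ended without GFP guide replicate 1 or 3 or Actg1 guide replicate 1 or 2 (limma adjusted p = 0.0893, 0.243, 0.0616 and 0.0656), and that of Krt19 without GFP guide replicate 2 or 3 or Actg1 guide replicate 2 (limma adjusted p = 0.0592, 0.114 and 0.117).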

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

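The 6-library fit, and the use of the thresholds and pseudocounts for promoters and of the pseudocounts for lists, were chosen after seeing the data; the other alternatives were planned. The count of called regions was 23248 to 29571 under 3 scalings (25277 to 25370), voom on estimated reads (28742), 2 filters, 2 pseudocounts, an FDR of 0.10 and 6 separate libraries (28176), and 17154 with a log2 change of at least 0.5. Leaving out single libraries gave 12793 to 24706, the lowest without GFP guide replicate 3, where the lone GFP guide sample is assumed to vary like the Actg1 guide samples. The scalings moved the median of all regions to between -0.0097 and 0.0152. Promoters were called less often than other regions under every alternative run (odds ratio 0.17 with the log2 bound of 0.5, 0.39 without GFP guide replicate 3, and up to 0.72 with a 5 kb promoter window). Camera called 0 lists wherever it was run. Of the 5 lists called by fry, 0 to 5 were still called under 17 alternatives, with 0 at the 5 kb window, where the interferon list turned upward. The summed signal near Actg2 moved from 0.03 to 0.11 (log2) with the 50 kb window, which holds 3 more regions. No named region changed sign with a call, and 1, Mylpf, gained a call, under 4 alternatives. Of the 136 named regions, 36 were no longer called without GFP guide replicate 3 and 2 to 10 without any other library. With the replicate number as a block, 28725 regions were called (14322 higher, 14403 lower). Same-numbered libraries deviated together at r = 0.0252, 0.0138 and 0.0161, so the numbers were not taken as pairs, although every library correlated best with its own number, a hint from the data only. The gene bodies of both actin genes and the 10 kb around Actg1 gave no value. Tests needing raw counts, GC corrections (with or without the replicate block), motif sets, similarity to the Actg1 mRNA and the threshold of an authors' test were not run. In the simulation, 6% of the changes of the smallest size were called.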

Other observations

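The tests of other splits, depth, starting cells, chromosome X and chromosome 1 were chosen after the results were seen, as were the 4 added gene lists themselves; the bounds for chromosome segments and for genes near a rise were set before those values were computed. Those for the 4 lists were also set before, then briefly rewritten after their results had been seen, and are used here in their first wording.

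Beyond the lists fixed beforehand, homeobox, antigen presentation and matrix genes held called promoters. Over all promoter regions 32.7% were called, so called members alone do not set a list apart. Of 13 promoter regions of Hox genes, which set position along the body axis, 4 were higher and 1 lower. The region of Hoxa13 957 bp from its TSS rose from 104 ± 3.18 (SD, n = 2) to 171 ± 13.6 (SD, n = 3), while the one 154 bp from the TSS had a log2 fold change of -0.03 that did not pass (limma adjusted p = 0.816). Hoxa10 rose by 0.38 on the log2 scale, and Hoxd13 had -0.14. The rises at Hoxa10, Hoxa11 and Hoxa13 lay close together on chromosome 6, between 52240071 and 52260246, and may not be independent. Of 15 regions of antigen presentation genes other than Cd74, 5 were higher and 0 lower, with H2-D1 at 0.69 and H2-DMa at 0.59 in the region 849 bp from its TSS and 0.18 in that 27 bp from it. All 5 lay on chromosome 17, between 34000034 and 35263226, and may not be independent. Members on other chromosomes were not called. Of 20 regions of further matrix genes 3 were higher and 6 lower, with Thbs1 (thrombospondin) at 0.41, Col11a1 at -0.83 and Fbln5 (fibulin) at -0.58. Of 5 regions of the list of further sarcomere genes 1 was higher and 2 lower, with Pdlim5 at -0.21 and Flnc at 0.465 in the region 777 bp from its TSS. The other fall, at -0.79, was at Casq1, the gene of calsequestrin, which is not a sarcomere protein. The counts were lower without GFP guide replicate 3, which left 1 GFP guide sample. Without it, 2 regions were higher and 0 lower among Hox genes, 3 and 0 among antigen presentation genes, 2 and 3 among matrix genes, and 0 and 1 among sarcomere genes. The calls that ended were those of Hoxa10, Hoxa11 and Hoxd13 (limma adjusted p = 0.0532, 0.0729 and 0.268), of Tap2 and the H2-DMa region 27 bp from its TSS (0.199 and 0.0672), of Efemp2, Fbln2, Tnc and Col16a1 (0.144, 0.33, 0.461 and 0.0833), and of Flnc and Pdlim5 (0.182 and 0.0859). At Hoxa10, Hoxa11, H2-DMa, Efemp2, Flnc and Pdlim5 the log2 fold change stayed at 82.1% to 106% of its main value while the standard error rose, and at Hoxd13, Tap2, Fbln2, Tnc and Col16a1 it was 48.2% to 73.6%. The call of Hoxd13 also ended without GFP guide replicate 2 (0.209), without Actg1 guide replicate 2 (0.0759), after total scaling (0.0509) and after cyclic loess (0.0885). That of H2-K1 ended without GFP guide replicate 2 (0.0808), without each Actg1 guide replicate in turn (0.121, 0.127 and 0.0503) and after cyclic loess (0.0536). Leaving out other libraries ended further calls, among them Hoxc6, Tap2, Efemp2, Fbln2, Tnc and Flnc.

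The hypothesis that these groups moved as sets was tested with camera over the 4 lists. The adjusted p was 0.168 for Hox genes, 0.0685 for antigen presentation, 0.168 for matrix genes and 0.607 for sarcomere genes, and 0.258, 0.258, 0.258 and 0.637 with an estimated correlation. None passed camera, and with medians of 0.06, 0.18, -0.17 and -0.16 and 5 to 20 regions a group change stays open. Fry, which does not refer to other promoters, gave an unadjusted p of 0.00333 for Hox genes and 0.0505 for antigen presentation. For matrix and sarcomere genes fry gave 0.0111 and 0.00661, also unadjusted. Its mixed test gave 0.00109, 0.00681, 0.000105 and 0.00927 in the same order. Alternatives were not run for fry on these lists. The bound set beforehand against a Hox change, a median within 0.1 of 0, was met, but was poorly chosen because members called in both directions give such a median whether or not the group changed.

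The breadth of the difference, 25323 of 61327 regions, may have causes other than the guide's target. With 6 separate libraries the real grouping called 28176 regions and the other 9 of the 10 splits at most 0 (limma; 308 to 661 at an unadjusted p under 0.05), so 1 split reached the real count. The other splits keep the group difference in their residual, so their 0 calls decide nothing, and 10 splits are too few for a share under 0.05. Depth is argued against by the cross-group pair closest in depth, replicate 1 of each guide, whose chi-square per region was 6.87 against at most 1.13 within groups; an earlier test of the 3 deepest against the 3 shallowest libraries called 0 regions (463 at an unadjusted p under 0.05), but leaves the group difference in its residual and decides nothing. Gains or losses of long chromosome segments are argued against as the main cause. After the median change of neighbours within 2.5 Mb was taken off, 87.3% of calls were kept. Segments covering only a small part of that window would leave the median in place, so the test does not address them. Cell populations that differed before the guides were given cannot be told apart from an effect of the guide, because no library of the starting cells was used here. By at least 8-fold, 53 regions differed. The labels of the 3 Actg1 guide libraries carry the same guide name. Effects of that guide other than on Actg1 mRNA therefore cannot be told apart from effects of its target.

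The region that rose 3.75-fold at 33.8 kb from Actg2 was noticed in the data. Of 17870 protein-coding genes with a tested region within 50 kb, 512 (2.87%) had a region there that rose as much, and of the 1741 with 4 regions 35 (2.01%) did. A called rise of at least 2-fold lay near 19.8% of those 1741 genes. A rise as large as this one was less common, but that cut is the value of a region noticed for its rise. Over the genome 327 regions rose as much, so some of the 512 genes share a region. That the region acts on Actg2 is a hypothesis that was not tested, since RNA was not analysed here and Dguok is nearer.

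Signal on chromosome X was lower with the Actg1 guide, by a median log2 shift of -0.106 against the autosomes (95% bootstrap interval over 5 Mb segments -0.153 to -0.0597). X was picked as the lowest of 20 chromosomes, which this interval does not allow for. When the 5 Mb segments were dealt at random to the chromosomes, 0.05% of 2000 deals gave any chromosome as far from the rest as X. The deals treat segments as independent. Neighbouring segments may move together, so the deals cannot exclude chance spread between segments. Neither the interval nor the deals measure the spread between libraries, because both resample segments of the same fold changes. Chromosome 18, at -0.0755 against the rest, was also beyond most deals (share 0.014), so X is not the only chromosome that departs. On chromosome 11, at 0.0653, the share was 0.051. Autosome medians ranged from -0.0786 on chromosome 18 to 0.0549 on chromosome 11. A lower copy number of X in part of the cells would shift promoters and other regions alike. Promoters shifted by -0.153 and other regions by -0.0746, a difference of -0.0783 (interval -0.125 to -0.0346) that met the bound set against copy number. Yet the median at promoters minus that elsewhere was -0.104 on X, -0.134 on chromosome 13 and up to 0.0661 on chromosome 11, so X lies within the range of the autosomes and copy number stays open. No biological explanation was tested.

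Of the 15 named promoter falls, 7 lay on chromosome 1. Over all 55 falls of at least 2-fold at coding promoters the count there was also 7. Chromosome 1 holds 5.66% of coding promoters. Regions away from promoters did not fall by 2-fold more often there (Fisher's exact odds ratio 0.95, 95% interval 0.821 to 1.09, p = 0.502). An earlier test on the 40 other promoter falls, of which 0 lay on chromosome 1 (Fisher's exact p = 0.17), left out the called promoters that formed the pattern and decides nothing.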
